A study of Homo sapiens with 3 samples.

How the data were processed

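Human neuromusculoskeletal organoids made from the H9 embryonic stem cell line were profiled by single-nucleus RNA sequencing with 10x Genomics 3' chemistry. Per the labels' protocols, organoids of one stage were pooled and frozen, and nuclei were isolated from the frozen pools. There were 3 libraries, 1 at day 38, 1 of the neural compartment at day 56 and 1 at day 75. Each group therefore had 1 library, and no difference between groups had a replicate check.

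The deposited matrices held whole-number UMI counts per gene and nucleus barcode, made with Cell Ranger 6.1.2 per the file headers, on GRCh38 per the submitters' processing notes. The annotation release and the use of intronic reads were not given in the sources used here. The matrices listed 33538 genes, and the lowest barcode totals were 500, 504 and 500 UMIs at day 38, day 56 and day 75. The barcodes numbered 10459, 4700 and 7529, with 45544786, 17967794 and 41493000 UMIs.

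Nuclei were kept with at least 500 detected genes and at most 5% mitochondrial UMIs. Under 500 genes were found in 147, 8 and 346 barcodes, and over 5% mitochondrial UMIs in 32, 1 and 40. Doublets were treated with Scrublet (Scanpy 1.11.5), run on each library, by removing the barcodes with the highest scores at a rate of 0.8% per 1000 barcodes, which was 875, 177 and 453 barcodes. The kept nuclei numbered 9414, 4514 and 6714, with medians of 3302.5, 3132 and 4225 UMIs. Counts were scaled to 10000 per nucleus and log transformed. The 3 libraries were clustered together without batch correction on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2), giving 23 clusters. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

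Clusters were named from marker lists fixed before the data were examined, by the mean log2 ratio of a list's genes over the median of all clusters, with at least 3 markers at 2-fold or more. The scoring thresholds were set after the data had been seen. They required a score of at least 0.75 and left unnamed any cluster in which a list of another tissue scored above 0.6 of the best one. Clusters led by stress or cell cycle genes (3 of the top 10) were also left unnamed, as were those whose median share of mitochondrial and ribosomal protein UMIs was over 2 times the median over clusters, 1.12%. Kept out of the classes by these rules, the unnamed clusters held 16.6% of kept nuclei at day 38, 25.5% at day 56 and 22.9% at day 75. BAPX1 and PRRXL1, 2 listed symbols, were not matched.

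UMIs were summed per class and library and given as CPM, that is, scaled to a common total per class and library. Log2 ratios had exact 95% intervals from the binomial share of a gene's UMIs, shares of nuclei had Clopper-Pearson intervals, and differences of shares had Newcombe intervals. All of these cover counting error only. A class was compared where both libraries had at least 100 nuclei. Each gene list fixed beforehand was summarised by the median log2 ratio with a pseudocount of 10 CPM, and its percentile among 10000 random lists matched on expression in 20 bins describes these libraries only. Scaling by the median ratio over expressed genes would shift the log2 ratios by 0.13 in muscle fibre-like, 0.15 in chondrogenic-like, 0.12 in mesenchyme-like and 0.10 in neuron-like nuclei and by 0.12 between the day 75 and day 38 floor plate-like clusters, and ratios are given on the unshifted scale. Members were counted as 2-fold different where they had at least 50 UMIs over both libraries and an interval without 0. In simulated counts with 200 altered genes, 93.5% of the intervals of these altered genes held the true ratio for muscle fibre-like nuclei. Of the 11393 unaltered genes, 0 passed the 2-fold rule. Without replicate libraries, the simulation could not include measured differences between libraries of a stage. It checks the intervals and the rule against counting error only, and gives no rate of false 2-fold differences between stages.

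The genes named for a comparison were the 10 highest and 10 lowest by log2 ratio with that pseudocount, among genes with at least 100 UMIs and 50 CPM in the class where they were higher and at least 0.5 of the level in the other nuclei of that library. Mitochondrial, ribosomal protein, sex-linked marker, antisense and unnamed loci were left out. The 3 list members with the largest ratios were added, and other genes are said to have been chosen after their values were seen. Some genes that the rule names are not reported here. Clusters and ratios come from the same counts, so genes that separate clusters of different libraries also tend to have large ratios. All markers of the chondrogenic list are also members of the cartilage matrix list, and several muscle fibre markers are also in the sarcomere list. To compare shares of nuclei with a UMI, nuclei were thinned to 1000 UMIs, which left out 405, 82 and 522 nuclei, and a nucleus was called cycling with at least 3 UMIs of the cell cycle list. Coordinates come from GENCODE 29 on GRCh38, matched by gene identifier, which may not be the release the authors used.

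Alternatives fixed beforehand changed the gene and mitochondrial limits, the doublet step, the clustering, the naming of nuclei, the scaling, the pseudocount, the averaging and the thinning. Alternatives chosen after seeing the data left out the rule on mitochondrial and ribosomal protein UMIs, the mixed cluster, or all unnamed clusters.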

Results

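Single-nucleus RNA sequencing was carried out on organoids grown from H9, a human embryonic stem cell line, that were designed to hold neural, muscle and skeletal tissue. The 3 libraries came from day 38, from the neural compartment at day 56 and from day 75, with 1 library of pooled organoids each. Their total UMI counts ranged from 17967794 at day 56 to 45544786 at day 38, and 9414 nuclei at day 38, 4514 at day 56 and 6714 at day 75 were kept. With no replicates, values are set side by side without a test, and their 95% intervals cover counting error only. Levels are given as CPM, the UMIs of a gene scaled to a common total of each class and library, and differences as log2 ratios of CPM.

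The first comparison asked which cell classes made up the organoids at day 38 and day 75. Muscle nuclei were more frequent at day 75, and neural and skeletal nuclei were less frequent. Muscle progenitor-like and muscle fibre-like nuclei together made up 16.7% of nuclei at day 38 (Clopper-Pearson 95% interval 15.9 to 17.4) and 37.8% at day 75 (36.6 to 38.9), a difference of 21.1 percentage points (Newcombe interval 19.7 to 22.5). Neural classes made up 43.7% at day 38 and 24.4% at day 75, and skeletal classes 23.0% and 14.9%. The neural difference was -19.3 points and became -4.72 points when single nuclei were named by their own marker scores, -7.05 points with all doublet scores kept and -24.2 points with each library clustered on its own. The skeletal difference was -8.08 points, with -9.90 and -5.25 points under the last 2 of these alternatives. Most of the muscle difference lay in fibre-like nuclei, at 12.3% against 34.1%, whereas PAX7-expressing progenitor-like nuclei made up 4.36% and 3.63%. Chondrogenic-like nuclei made up 16.2% and 5.93%, and mesenchyme-like nuclei 6.80% and 8.97%. Different clusters held most of these classes in the 2 libraries: fibre-like nuclei came mainly from cluster 4 at day 38 and from clusters 2 and 13 at day 75. The share of each class depends on how many nuclei of each tissue survived isolation, which was not measured.

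**Figure D1:**
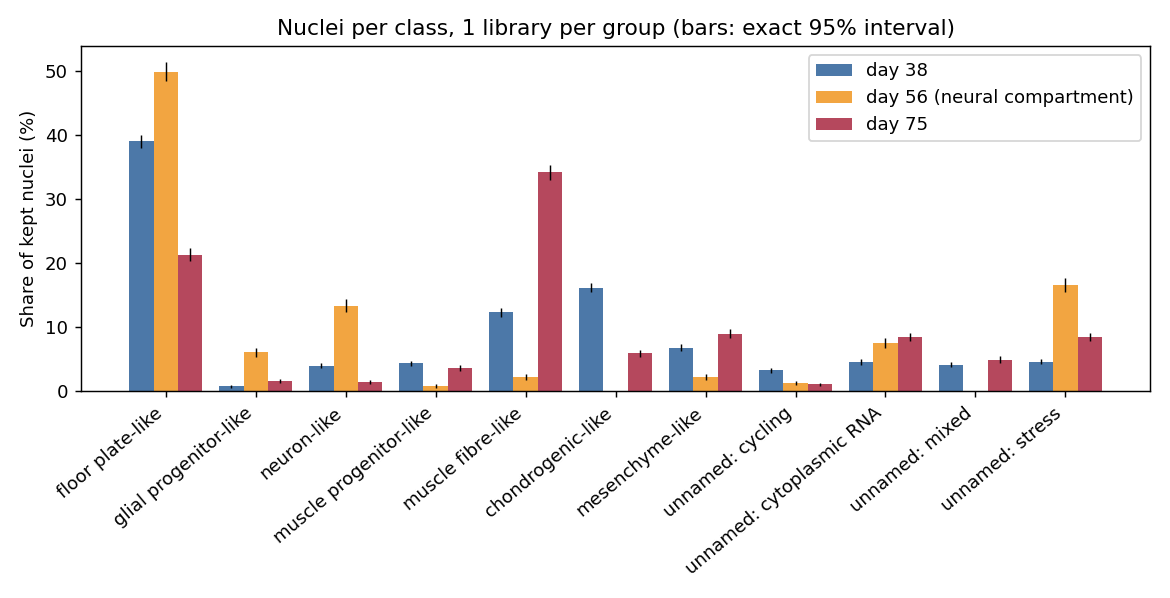
Share of kept nuclei (percent, vertical axis) in each named class and each group of unnamed clusters (horizontal axis) for the libraries of day 38, day 56 (neural compartment) and day 75, with exact 95% intervals as black lines. Fibre-like nuclei stood at 12.3% at day 38 and 34.1% at day 75.

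In muscle fibre-like nuclei (1159 at day 38, 2292 at day 75), most hypoxia and glycolysis genes and a minority of sarcomere genes were at least 2-fold higher at day 75, and 3 neuromuscular junction genes were at least 2-fold lower. ACTN3, the alpha-actinin of fast fibres, stood at 41.0 CPM at day 75 and 2.13 at day 38 (log2 ratio 4.27, interval 3.54 to 5.11). It lies on the plus strand of chromosome 11 at 66546395 to 66563329. The fast troponin gene TNNI2 (log2 ratio 1.69) and NRAP, which encodes a protein of developing myofibrils (1.92), were also higher. Of the 40 sarcomere genes with enough UMIs, 13 were at least 2-fold higher and 2 at least 2-fold lower, with a list median of 0.23 (interval 0.16 to 0.31). The median was 0.13 with median-ratio scaling and 0.15 averaged over nuclei, and 0.43 with single nuclei named and 0.47 without the rule on mitochondrial and ribosomal protein UMIs. Among myosin heavy chains, chosen after their values were seen, perinatal MYH8 was higher at day 75 (1487 against 494 CPM, log2 ratio 1.59). Embryonic MYH3 remained the more abundant of the pair at day 75 (6156 against 8020 at day 38, log2 ratio -0.38).

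The hypoxia and glycolysis list had the highest median of the lists in fibre-like nuclei, 1.13 on the log2 scale, and 21 of its 23 members with enough UMIs were at least 2-fold higher at day 75. GAPDH (chromosome 12, 6533927 to 6538374, plus strand) stood at 498 against 84.9 CPM, a log2 ratio of 2.55 (interval 2.43 to 2.67). In the other nuclei GAPDH stood at 481 against 115 CPM, and in mesenchyme-like nuclei at 463 against 89.7 CPM, so its rise was not particular to fibre-like nuclei. Other nuclei are all kept nuclei of a library outside the class. For fibre-like nuclei they include the muscle progenitor-like nuclei and unnamed cluster 15, led by muscle genes, with 540 nuclei at day 75 and 15 at day 38. The neuronal enolase gene ENO2 (2.97) and the lactate dehydrogenase gene LDHA (2.18) were higher as well. In excitation contraction coupling and muscle metabolism, 11 of 25 members were at least 2-fold higher and 1 lower, with a median of 0.58. Among the higher were the muscle creatine kinase gene CKM (2.40), the sodium channel gene SCN4A (2.52) and sarcolipin, SLN (2.20). This list also had medians of 0.53 in chondrogenic-like, 0.48 in muscle progenitor-like and 0.43 in mesenchyme-like nuclei, and 0.25 in floor plate-like clusters. In the other nuclei, with cluster 15 among them, CKM stood at 211 against 42.9 CPM. The hypoxia and glycolysis list also had medians of 0.80 in chondrogenic-like, 0.62 in mesenchyme-like and 0.28 in muscle progenitor-like nuclei, and 0.32 in floor plate-like clusters.

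Of the 21 neuromuscular junction genes measured well enough in fibre-like nuclei, 1 was at least 2-fold higher and 3 at least 2-fold lower, with a median of -0.12 (interval -0.21 to -0.07). That median lay inside the range of matched random lists, -0.13 to 0.29, at percentile 3.15. The median was -0.23 with median-ratio scaling and -0.24 averaged over nuclei. CHRNA1, which encodes the alpha subunit of the muscle acetylcholine receptor (chromosome 2, 174747592 to 174787935, minus strand), stood at 134 CPM at day 75 and 304 at day 38 (log2 ratio -1.18). COLQ, the collagen tail of acetylcholinesterase, was lower (-1.55) and the laminin gene LAMA5 was higher (1.81). The receptor kinase gene MUSK, chosen after its value was seen, was lower (-0.80). Among the genes named by size were the higher ANKRD9 (4.91) and COL19A1 (3.60) and the lower FUT9 (-4.05), CD96 (-3.66) and GRIA4, a glutamate receptor subunit gene (-3.29). In the other nuclei ANKRD9 (17.2 against 1.70 CPM) and COL19A1 (48.3 against 8.08) were also higher at day 75, and CD96 (9.13 against 45.3) lower. In the neuron cytoskeleton and growth list 15 of 17 members were at least 2-fold lower, including DCX (-2.06), SEMA6D (-1.49) and ROBO1 (-1.48), and 1 was higher. The list was also lower in other classes, with medians of -0.60 in chondrogenic-like, -0.48 in floor plate-like, -0.35 in mesenchyme-like and -0.16 in muscle progenitor-like nuclei. The muscle progenitor-like median lay inside the range of matched random lists, -0.18 to 0.20. Neuron-like nuclei, which express the genes of this list, made up 3.97% of the day 38 library and 1.43% of the day 75 library.

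**Figure D2:**
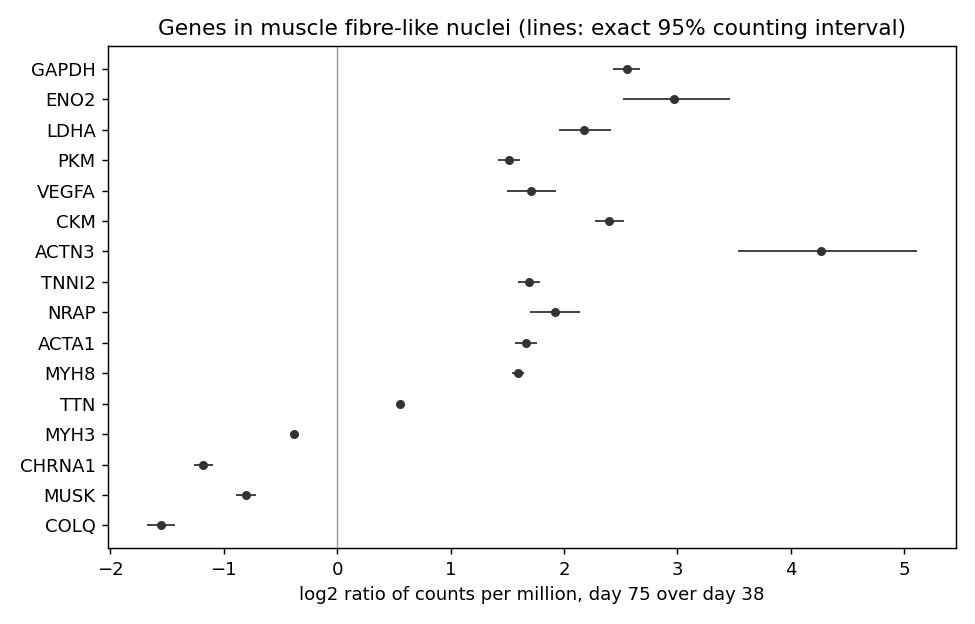
Log2 ratio of CPM at day 75 over day 38 (horizontal axis) for selected genes in muscle fibre-like nuclei (vertical axis), with points for ratios and lines for exact 95% counting intervals. ACTN3 lies farthest to the right at 4.27 and COLQ farthest to the left at -1.55.

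Muscle progenitor-like nuclei (410 and 244) differed between the days in single genes of the matrix and of the sarcomere. The laminin gene LAMA2 was higher (log2 ratio 2.61), as were COL19A1 (2.59) and COL15A1 (2.76), and the receptor kinase gene ALK was lower (-2.85). These matrix genes were also higher in the other nuclei of the day 75 library, fibre-like nuclei included. LAMA2 stood at 910 against 310 CPM, COL19A1 at 90.4 against 7.41 and COL15A1 at 34.8 against 11.5. In the mesenchyme and connective tissue list, 4 of 20 members were at least 2-fold higher and 1 lower, with a median of 0.20. Of 31 sarcomere genes, 11 were at least 2-fold higher, among them MYBPC2 (2.91) and MYH8 (1.87). The sarcomere list had medians of 0.35 in these nuclei, 0.44 in mesenchyme-like and 0.27 in chondrogenic-like nuclei, beside the larger share of fibre-like nuclei at day 75. Its median was 0.23 in floor plate-like clusters, as in fibre-like nuclei. PAX7, the transcription factor that marks satellite cells, stood close to its day 38 level, with a log2 ratio of -0.17 (interval -0.34 to -0.01). The share of thinned progenitor-like nuclei called cycling was 18.0% at day 38 (14.4 to 22.1) and 15.9% at day 75 (11.4 to 21.4), a difference within the counting intervals. The unthinned shares were 34.4% and 26.2%.

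Chondrogenic-like nuclei (1523 and 398) carried less cartilage matrix RNA at day 75, but this result depended on how nuclei were assigned and on the removal of doublets. In the cartilage matrix list, 16 of 23 members were at least 2-fold lower and 3 higher, with a median of -1.07 (interval -1.19 to -1.02). The collagen genes COL2A1 (941 against 1966 CPM, log2 ratio -1.06) and COL11A1 (-1.64) were lower, as was the proteoglycan gene EPYC (-3.20). COL2A1, chosen with COL11A1 after their values were seen, lies on the minus strand of chromosome 12 at 47972965 to 48004554. RUNX2, a transcription factor of bone formation, was higher (2.48), as were COL1A2 (2.40) and the limb mesenchyme gene PRRX1 (3.50). In the hypertrophy and ossification list 5 of 10 members were at least 2-fold higher and 2 lower, with a median of 0.23, and in the mesenchyme and connective tissue list 10 of 24 were higher and 0 lower. The glypican gene GPC3 was among the lowest (-3.92). The cartilage matrix list was also lower in mesenchyme-like (-0.56) and muscle fibre-like nuclei (-0.56) and in floor plate-like clusters (-0.57). The chondrogenic-like nuclei came from clusters 7 and 16 at day 38 and from cluster 20 at day 75, and COL11A1 and EPYC were among the top 10 genes of cluster 7 and RUNX2 among those of cluster 20. With each library clustered on its own the list median was 0.75, the ratio of PRRX1 was -0.86, and the median at Leiden resolution 2 was -0.04. With all doublet scores kept it was -0.15.

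Mesenchyme-like nuclei (640 and 602) differed between the days in several matrix genes. COL1A2 was higher (log2 ratio 1.88), as were COL12A1 (2.06), PRRX1 (2.10) and the protease inhibitor gene TIMP3 (3.25). In the mesenchyme and connective tissue list 11 of 23 members were at least 2-fold higher and 0 lower, with a median of 0.65. RFX4 (-2.65) and SLIT1 (-3.52) were among the lowest genes, but with a minimum of 1000 genes per nucleus their ratios were 1.48 and 0.32. The nuclei were mainly those of cluster 9 at day 38 and of cluster 14 at day 75, where COL1A2 and TIMP3 were among the top 10 genes.

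The neural compartment of day 56 was set beside the neural nuclei of the other libraries, and dissection and day cannot be told apart in it. Neural classes made up 69.3% of its nuclei (67.9 to 70.6), with 13.4% neuron-like and 6.07% glial progenitor-like nuclei. The neuron-like share and ratios leave out 336 day 56 nuclei of cluster 21, unnamed for its mitochondrial and ribosomal protein UMIs. The neuron list scored highest in that cluster (1.72, with 11 of 14 markers at 2-fold or more). Muscle classes made up 3.06% and skeletal classes 2.19%. Naming single nuclei gave a neural share of 36.4%. The median share of mitochondrial and ribosomal protein UMIs was 0.48% in the day 56 library, against 1.17% at day 38 and 0.997% at day 75. Neuron-like nuclei made up 3.97% at day 38 and 1.43% at day 75, where 96 nuclei were too few for ratios.

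Floor plate-like clusters held most of the neural nuclei of every library, but this depended on how nuclei were assigned, above all at day 75. Their share was 39.0% at day 38, 49.8% at day 56 and 21.3% at day 75. It was 27.2%, 49.3% and 0% with each library clustered on its own. With single nuclei named it was lower in every library, at 7.98% at day 56 and 3.31% at day 75, below the glial progenitor-like share in both. Each of the floor plate-like clusters had 0 of the listed floor plate markers among its top 10 genes. Cluster 3, with most of the day 75 nuclei, had a glial marker there. The clusters were summed as 1 class per library. Clusters 0, 1, 3 and 6 together gave 3671 nuclei at day 38, 2249 at day 56 and 1431 at day 75, mainly from clusters 0 and 6, cluster 1 and cluster 3 in turn. GFAP, an intermediate filament gene of astroglia (chromosome 17, 44903161 to 44916937, minus strand), stood at 84.2 CPM at day 75 and 0.436 at day 38 (log2 ratio 7.59, interval 6.46 to 9.05). The glutamate transporter gene SLC1A2 (2.25) and SPARCL1 (1.27) were higher as well, and 4 of 15 gliogenesis genes were at least 2-fold higher and 0 lower. The list median of 0.20 changed sign when members under 50 UMIs were left out (-0.08) and when single nuclei were named (-0.14). PAMR1 (4.04) and COL21A1 (3.08) were higher, and the axon guidance receptor gene DCC was lower (-2.42). DCC was also lower in the other nuclei of the day 75 library, at 53.7 against 258 CPM. GFAP was among the genes that set cluster 3 apart, so its ratio also describes that cluster. GFAP was also higher in mesenchyme-like nuclei (3.48), which are not glial. The top 10 genes of clusters 1 and 3 included the cilia genes VWA3A and ZBBX. DNAH12, CFAP46, CFAP54 and CFAP299 were also there in cluster 1, and CFAP52 and TEKT1 in cluster 3. CFAP54, chosen after its value was seen, was found in 52.2%, 63.7% and 45.1% of thinned floor plate-like nuclei at day 38, day 56 and day 75. In neuron-like nuclei the shares were 10.7%, 16.3% and 3.13%, and in fibre-like nuclei 3.20%, 17.8% and 0.833%.

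HOX genes of paralogs 1 to 4 had a list median of 0.39 in floor plate-like clusters for day 56 over day 38. Of 9 members, 3 were at least 2-fold higher and 0 lower. The list was also higher in neuron-like nuclei (median 0.36). Summed paralogs 1 to 4 were higher in muscle classes (365 against 150 CPM) and skeletal classes (583 against 442 CPM) too. HOXB4 (chromosome 17, 48575513 to 48580111, minus strand) stood at 149.9 against 48.4 CPM, a log2 ratio of 1.63, and HOXB8 was higher (1.77). The floor plate regulator FOXA2 was higher (1.65), whereas SHH, chosen after its value was seen, was close to its day 38 level (0.16, interval -0.06 to 0.37). The floor plate gene CORIN, also chosen after its value was seen, was lower, at 158 against 347 CPM. TTR (2.28), PCDH15 (2.55) and CLU (1.83) were also higher, as they were in the other nuclei of that library (98.47 against 28.95, 530 against 208 and 186 against 55.5 CPM). Against day 75, TTR had a log2 ratio of 4.72 and GFAP of -4.06. Of 39 synapse genes in these clusters, 17 were at least 2-fold higher at day 56 than at day 38 and 1 lower, with the potassium channel gene KCND2 (2.80) among the higher. Neuron-like nuclei were also more frequent in that library, at 13.4% against 3.97%. Of 34 sarcomere genes, 29 were at least 2-fold lower and 0 higher, with a list median of -1.52, and MYLPF, a fast myosin light chain gene, had a ratio of -4.17.

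**Figure D3:**
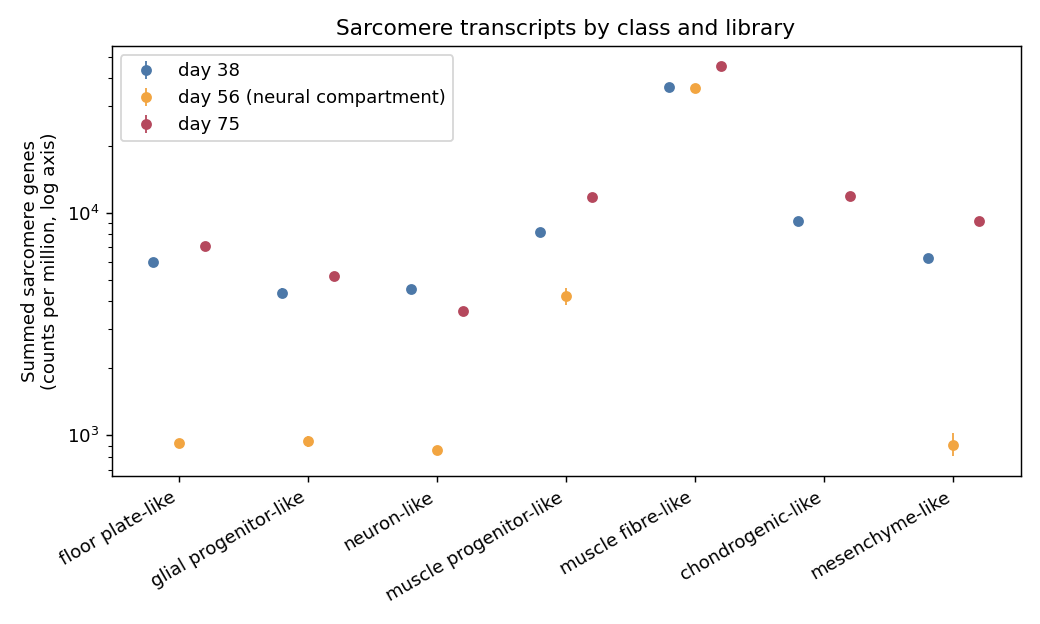
Summed CPM of the sarcomere list (vertical axis, log scale) in each class (horizontal axis) and library, with exact Poisson 95% intervals. Floor plate-like clusters stood at 6014 at day 38, 924 at day 56 and 7079 at day 75, while fibre-like nuclei stood between 36190 and 45649.

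In neuron-like nuclei (603 at day 56, 374 at day 38), several stress response and glycolysis genes were at least 2-fold higher at day 56. Of 14 genes of the unfolded protein and stress response, 8 were at least 2-fold higher and 0 lower, with a median of 0.58, including DDIT4 (3.86) and ASNS (1.45). The same list had a median of 0.33 in floor plate-like clusters, with 6 of 19 members higher and 0 lower, and stress-led clusters held 16.6% of the day 56 and 4.64% of the day 38 nuclei. In cluster 10, led by stress genes and with 733 day 56 nuclei, the neuron list scored higher than the other class lists. In the hypoxia and glycolysis list 7 of 20 members were at least 2-fold higher and 1 lower, with VEGFA (2.97) and ENO2 (1.78) among the higher. VEGFA stood at 101 against 12.9 CPM in neuron-like and at 107 against 20.1 CPM in the other nuclei, and the list median was 0.53 in neuron-like nuclei and 0.15 in floor plate-like clusters. The synapse list had a median of 0.11 (interval 0.02 to 0.16), with 3 of 43 members at least 2-fold higher, SCN1A (1.32), GRIN1 (1.17) and DLG4 (1.08). The synapse median lay inside the range of matched random lists, -0.13 to 0.16, at percentile 91.6. Without the rule on mitochondrial and ribosomal protein UMIs the synapse median was -0.02, and with single nuclei named it was 0.41. HES4 (5.18, interval 3.61 to 7.46) and the neuropeptide precursor gene VGF (3.18) were among the highest genes. HES4 was also higher in the other nuclei of that library, at 40.4 against 1.12 CPM, and VGF at 12.9 against 1.34 CPM.

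Glial progenitor-like nuclei of cluster 17 (274 at day 56, 112 at day 75) differed between the days in single astroglial genes. GFAP stood at 163 against 545 CPM (log2 ratio -1.74), and was also lower in the other nuclei at day 56, at 7.65 against 25.5 CPM. AQP4, a water channel gene of astrocytes, was lower (-3.19, interval -4.39 to -2.15), as was HOPX (-2.34). Of 14 gliogenesis genes, 5 were at least 2-fold lower at day 56 and 1 higher, with a list median of -0.20 (interval -0.39 to -0.09). The growth factor gene VEGFA was higher (3.42), as were 10 of 25 synapse genes, including GRIN2A (3.09), while 2 were lower. In floor plate-like clusters 20 of 38 synapse genes were at least 2-fold higher at day 56 than at day 75 and 0 lower, and neuron-like nuclei were more frequent in the day 56 library (13.4% against 1.43%). PLPPR1 and CDH18 (2.54) were among the higher genes, but with each library clustered on its own their ratios were -1.25 and -1.72.

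Motor neuron markers were concentrated in 1 of the 2 neuron-like clusters. Cluster 22 had 6 of 10 motor neuron markers at 2-fold or more, including CHAT, the enzyme of acetylcholine synthesis, at 78.9 CPM against 7.95 in cluster 8, and ISL1 at 95.6 against 5.16. It also had 4 of 12 sensory neuron markers at 2-fold or more (NTRK2, NTRK3, PRPH and RET), against 2 in cluster 8. TPH2, which encodes the enzyme of neuronal serotonin synthesis and was chosen after its value was seen, stood at 101 in cluster 8 and 3.55 in cluster 22. Among thinned neuron-like nuclei, 37.5% at day 38 (32.6 to 42.7), 37.9% at day 56 (34.0 to 41.9) and 44.8% at day 75 (34.6 to 55.3) had a UMI of any motor neuron marker. The marker found most often was SLIT3 (29.5%, 27.6% and 24.0%), which was also found in 11.2% of floor plate-like nuclei at day 38, followed by SLC5A7 (7.77%, 9.80% and 19.8%) and ALDH1A2 (6.97%, 9.63% and 18.8%), all chosen after their values were seen. CHAT was found in 1.61%, 2.16% and 7.29% and ISL1 in 3.22%, 3.49% and 0%. In fibre-like nuclei, taken as background, the shares with any motor neuron marker were 9.07%, 10.9% and 9.12%. In floor plate-like clusters they were 14.2%, 9.35% and 4.68%. Median depths were 4394, 5764 and 8608 UMIs in neuron-like and 5611, 5182 and 6405.5 in fibre-like nuclei, and unthinned neuron-like shares were 63.1%, 70.5% and 80.2%. CHAT stood at 23.4 CPM at day 38 (17.2 to 31.1), 31.7 at day 56 (26.6 to 37.4) and 67.2 at day 75 (52.8 to 84.4) in neuron-like nuclei. ISL1 stood at 31.3, 47.3 and 21.8 CPM and MNX1 at 20.9, 14.2 and 15.4 CPM in the same order. Cluster 22 held 97 of 374 neuron-like nuclei at day 38, 147 of 603 at day 56 and 41 of 96 at day 75.

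HOX genes of anterior paralog groups dominated in every tissue. In neural classes, paralogs 1 to 4 made up 90.2% of HOX UMIs at day 38, 87.1% at day 56 and 91.0% at day 75. Paralogs 9 to 13 made up 0.103% (0.0547 to 0.175), 0.298% and 0.509%. Muscle classes had 84.8% and 86.3% from paralogs 1 to 4 at day 38 and day 75, and skeletal classes 87.3% and 91.7%. These paralogs stood at 150 and 176 CPM in muscle and 442 and 425 CPM in skeletal classes. In neural classes they stood at 708 and 646 CPM. RNA from other tissues was not separated from these levels.

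Cycling nuclei were more frequent at day 38. After thinning, 5.16% of nuclei at day 38 (4.71 to 5.64), 2.55% at day 56 and 2.58% at day 75 (2.20 to 3.01) had at least 3 UMIs of the cell cycle list. Without thinning the shares were 19.1%, 12.0% and 10.7%. The list's level was 643, 396 and 348 CPM. Without the unnamed clusters, which include the one led by cell cycle genes, the share at day 75 minus that at day 38 was smaller in size, at -1.12 points. Among floor plate-like clusters, 12 of 23 cell cycle genes were at least 2-fold lower at day 75 than at day 38, including KIF14 (log2 ratio -2.21). KIF14 alone stood at 165 CPM there at day 38, where the whole list stood at 384 CPM and 1.75% of thinned nuclei were called cycling. It was also lower in the other nuclei at day 75, at 17.7 against 54.2 CPM.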

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

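The listed differences and groups of nuclei were picked out by rules of size, and none was weighed against technical explanations. The neuromuscular junction list had medians of 0.22 (interval 0.04 to 0.38) in muscle progenitor-like and -0.12 (interval -0.21 to -0.07) in muscle fibre-like nuclei for day 75 over day 38. Each median lay inside the range of matched random lists, -0.18 to 0.25 for progenitor-like and -0.13 to 0.29 for fibre-like nuclei. The difference of 0.34 was not tested.

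Several clusters held nuclei that entered no class comparison. Nuclei of clusters led by stress genes such as HSPA1A, HSPH1 and GADD45B made up 16.6% of the day 56 library (15.5 to 17.7), against 4.64% at day 38 and 8.46% at day 75. Nuclei rich in mitochondrial and ribosomal protein UMIs reached 8.43% at day 75 (7.78 to 9.12), where most were led by muscle genes such as MYH8 and CKM. They made up 7.55% at day 56, where 336 of 341 were in cluster 21, which scored highest for the neuron list. At day 38 they made up 4.54%, and 412 of 427 were in cluster 19, which scored highest for the chondrogenic list. The cluster with markers of several tissues, including COL1A2 and COL9A1, made up 4.94% at day 75 (4.44 to 5.49), with a median of 14632 UMIs. The cluster led by cell cycle genes such as TOP2A and ASPM made up 3.29% at day 38 (2.94 to 3.67). Its best-scoring list was the chondrogenic one (1.43, with 11 of 17 markers at 2-fold or more).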

How the results depend on the processing

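The alternatives were fixed before the data were examined, except for those said to have been chosen after seeing the data. Of the values that answer a comparison, 94 stayed within their counting intervals under the alternatives, 50 moved beyond them and 4 reversed. Of the ratios of named genes and the shares of single classes, 1592 stayed, 486 moved and 30 reversed. Gene lists whose medians are not among the values that answer a comparison were not run under the alternatives. Muscle nuclei were more frequent at day 75 under every alternative run, by 16.5 to 29.02 points, and neural nuclei less frequent, by -24.2 to -4.72 points. The fibre-like medians kept their signs, at 1.06 to 1.54 for hypoxia and glycolysis, 0.13 to 0.47 for the sarcomere and -0.24 to -0.09 for the neuromuscular junction. The hypoxia and glycolysis list was fixed beforehand, but its median joined the values that answer a comparison after it was seen. Shares below are day 75 minus day 38 in percentage points unless given for day 56. List values are the medians given in the report: gliogenesis in floor plate-like clusters, cartilage matrix in chondrogenic-like nuclei, synapse and excitability in neuron-like nuclei and the others in fibre-like nuclei. Gene ratios are day 75 over day 38, or day 56 over day 75 in glial progenitor-like nuclei. The cause of these shifts was not tested.

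A minimum of 1000 genes gave 24.7 points for the muscle share, -6.56 points for the skeletal share, 75.6% for the neural share of day 56 and 33.1% for the motor marker share of day 56. It reversed the ratios of C8orf34 (1.62), CDHR3 (1.13), DOCK3 (1.14), GRIK4 (1.01), KIRREL3 (0.78), RFX4 (1.48), SLIT1 (0.32) and STK33 (0.49) in mesenchyme-like nuclei. A limit of 2% mitochondrial UMIs gave -17.3 points for the neural share, 70.8% for the neural share of day 56 and 0.10 for the gliogenesis list. Keeping all doublet scores gave -7.05 points for the neural share, -9.90 points for the skeletal share, 72.6% for the neural share of day 56, 0.0751 for the gliogenesis list and -0.15 for the cartilage matrix list. It reversed the ratios of C8orf34 (1.35), CDHR3 (0.88), DOCK3 (1.01), GRIK4 (0.74), ITGBL1 (-0.77), KIRREL3 (0.78), RFX4 (1.12), SLIT1 (0.47) and STK33 (0.51) in mesenchyme-like nuclei. Leiden resolution 2 gave -15.1 points for the neural share, 71.1% for the neural share of day 56, 0.29 for the gliogenesis list and -0.0437 for the cartilage matrix list. It reversed the ratios of PDZRN4 (-0.0682) in chondrogenic-like nuclei. Ratios also reversed for ITGBL1 (-0.0688) in mesenchyme-like nuclei. Clustering each library on its own gave -24.2 points for the neural share, -5.25 points for the skeletal share, 71.0% for the neural share of day 56 and 0.75 for the cartilage matrix list. It reversed the ratios of ADGRD2 (-0.66), CDH18 (-1.72), EFNB3 (-0.20), PLPPR1 (-1.25) and TTC6 (-1.80) in glial progenitor-like nuclei. Ratios also reversed for PDZRN4 (-0.28), PRRX1 (-0.86) and RBFOX1 (-2.07) in chondrogenic-like nuclei. Naming single nuclei gave -4.72 points for the neural share, 16.5 points for the muscle share, 36.4% for the neural share of day 56, -0.14 for the gliogenesis list, 0.41 for the synapse and excitability list, 0.43 for the sarcomere list, -1.29 for the cartilage matrix list and 32.2% for the motor marker share of day 56. It reversed the ratios of CDH18 (-0.13) and PLPPR1 (-0.0652) in glial progenitor-like nuclei. Ratios also reversed for ARHGEF28 (-0.21) in chondrogenic-like nuclei. Using a larger set of variable genes gave 67.5% for the neural share of day 56. Median-ratio scaling gave 0.13 for the sarcomere list, -0.23 for the neuromuscular junction list and -1.21 for the cartilage matrix list. A pseudocount of 1 gave 0.52 for the gliogenesis list, 0.30 for the sarcomere list and 1.54 for the hypoxia and glycolysis list. Averaging over nuclei gave 0.15 for the sarcomere list, -0.24 for the neuromuscular junction list and 1.31 for the hypoxia and glycolysis list. Leaving out list members under 50 UMIs gave -0.0836 for the gliogenesis list and 1.25 for the hypoxia and glycolysis list. Thinning to 2000 UMIs gave -6.62 points for the cycling share and 50.2% for the motor marker share of day 56. No thinning gave -8.43 points for the cycling share and 70.5% for the motor marker share of day 56. Requiring 2 cell cycle UMIs gave -5.76 points for the cycling share. Without the rule on mitochondrial and ribosomal protein UMIs, chosen after seeing the data, the analysis gave 28.99 points for the muscle share, 76.7% for the neural share of day 56, -0.0166 for the synapse and excitability list, 0.47 for the sarcomere list and 30.9% for the motor marker share of day 56. Leaving out all unnamed clusters, also chosen after seeing the data, gave -20.8 points for the neural share, 29.02 points for the muscle share, 93.0% for the neural share of day 56 and -1.12 points for the cycling share.

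Leaving out the mixed cluster, chosen after seeing the data, moved none of the values that answer a comparison beyond its interval. Chondrogenic-like ratios could not be given with at least 1000 genes or at most 2% mitochondrial UMIs, nor floor plate-like ratios against day 75 with each library clustered on its own, because under 100 nuclei were left in a library. No paired analysis was possible because each group had 1 library. With 96 nuclei at day 75, neuron-like ratios against that library were not given.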

Other observations

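The bounds for all 6 tests were set before their results were seen, while the patterns themselves were found in these data. Other gene lists also differed. In mesenchyme-like nuclei 6 of 10 stress response genes were at least 2-fold higher at day 75 than at day 38, among them TRIB3 (log2 ratio 2.46), SESN2 and ASNS, with a median of 0.47 (interval 0.32 to 0.63). In floor plate-like clusters, HOX paralogs 1 to 4 had a median of 0.60 (interval 0.45 to 0.66) for day 56 over day 75. Of 8 members, 4 were at least 2-fold higher and 0 lower, led by HOXB2. The same list had a median of 0.45 in glial progenitor-like nuclei. In neuron-like nuclei the cholinergic and motor neuron list had a median of 0.31 for day 56 over day 38, with AGRN (1.32) and PRPH (1.45) higher and LHX4 lower (-1.37).

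Sarcomere transcripts were found in floor plate-like clusters at 6014 CPM at day 38 and 7079 at day 75, against 924 in the day 56 library, which held few muscle nuclei. Doublets with muscle nuclei would gather these UMIs in few nuclei, but the 5% of day 38 floor plate-like nuclei with most held 12.0% of them (interval 11.2 to 12.8), and chance alone would give 9.38%. Free RNA from muscle remains a candidate explanation. Summed sarcomere levels differed among floor plate-like, neuron-like and mesenchyme-like nuclei by 1.38 times at day 38, under the bound of 2 that free RNA had to meet at both days. At day 75 they differed by 2.54 times (interval 2.47 to 2.63), between that bound and the bound of 3 set against it. The bounds took no account of depth, although free RNA adding like counts per nucleus gives lower CPM in deeper nuclei. Median depths at day 75 were 8608 UMIs in neuron-like, 3914 in floor plate-like and 2656 in mesenchyme-like nuclei. The bounds therefore cannot decide for or against free RNA. No biological explanation was tested.

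Hypoxia and glycolysis genes such as GAPDH and LDHA were higher in muscle fibre-like nuclei at day 75. More RNA from outside the nucleus may contribute, though the median share of mitochondrial and ribosomal protein UMIs in fibre-like nuclei was close, at 0.794% at day 38 and 0.819% at day 75. Among fibre-like nuclei lowest in these UMIs, 596 at day 75 and 267 at day 38, the list median was 0.83 (interval 0.69 to 0.93). That interval crosses the bound of 0.75 set against that explanation. Free RNA also stays open, since floor plate-like clusters showed 31.5% (interval 29.7 to 33.5) of the difference in summed CPM, between the bounds of 25% and 50%. These bounds took no account of depth either, with day 75 medians of 3914 UMIs in floor plate-like and 6405.5 in fibre-like nuclei. A difference between the stages was not tested apart from these.

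Cartilage matrix genes such as COL2A1 and EPYC were lower in chondrogenic-like nuclei at day 75. The values argue against less free cartilage RNA, because floor plate-like clusters showed 5.93% (interval 5.73 to 6.14) of the difference in summed CPM, below the bound of 25%. That bound also took no account of depth, with day 38 medians of 3382 UMIs in floor plate-like and 2189 in chondrogenic-like nuclei. The choice of nuclei called chondrogenic-like remains a possible explanation. With single nuclei named the median was -1.29, past the bound set against that explanation. That bound covered 1 way of naming only, and clustering each library on its own gave 0.75. The chondrogenic markers that name nuclei are also members of the cartilage matrix list, so naming by them cannot decide this. The removal of doublets also mattered, since keeping all doublet scores gave -0.15. A difference between the stages stays open and untested.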
